A study of Homo sapiens with 2 samples.

How the data were processed

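The series holds 10x Genomics 3′ v2 single-cell libraries of myeloid cells that were sorted by flow cytometry from enzymatically digested human kidney tissue, 1 library of a renal adenocarcinoma lesion and 1 of juxtatumoral tissue. The deposited matrices hold UMI counts per gene and barcode with no normalization, for 33694 genes and all 737280 barcodes of the barcode whitelist, so no cell filter had been applied. Per the submitters' processing notes they were made with Cell Ranger (version not given in the sources used here) against GRCh38, and Seurat 3 was used downstream. Each matrix holds whole numbers only, and no count was changed before the steps below.

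Analyses used Python 3.11.15 with scanpy 1.11.5, anndata 0.12.19, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0, python-igraph 0.11.9 and matplotlib 3.10.9, and gene positions are from GENCODE 29. The rules for cells, classes, lists, named genes and most of the other settings tried were fixed before the data were examined, except where a later choice is named. A barcode was kept as a cell when it had at least the larger of 500 UMIs and 0.1 times the 99th percentile of UMIs among the 3000 barcodes with most UMIs of its library, at least 200 detected genes and at most 20% mitochondrial UMIs. The resulting minimum was 1922 UMIs in the juxtatumoral and 2007 in the tumor library, with 2208 and 11574 barcodes at or above it. Doublets were called with Scrublet in each library at an expected rate of 0.8% per 1000 cells. It called 13 of 2192 juxtatumoral cells, 0.593% against 1.75% expected, and 1 of 11564 tumor cells, 0.00865% against 9.25% expected, so doublets of the tumor library were hardly removed. The kept cells held 81.8% of the UMIs of the juxtatumoral and 88.8% of the UMIs of the tumor library.

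Cells of both libraries were clustered together without batch integration: scaling to 10000 UMIs, log1p, 2000 variable genes, 30 principal components, 15 neighbours, Leiden resolution 1 and seed 0. Clusters were named from fixed marker lists of 20 cell types, of which 197 markers were in the files, and the genes leading each cluster. The plan left the exact naming rule open, and the rule used was settled after several versions had been seen on the clusters. A cluster took the class with most markers raised at least 1.5-fold against all other cells, at 10 CPM or more, and needed at least 3 of these. Its 10 leading genes against clusters with another best class had to hold at least as many markers of that class as of any other. It was left unnamed when its 10 leading genes against all other cells held 3 or more markers of another class and fewer of its own, when another class was level with its own in both comparisons, or when its cells held little RNA for their library and no such marker. Leading genes needed at least 50 CPM and detection in at least 10% of cells, the last condition being added because the hemoglobin RNA of 1 droplet in each library had kept cluster 8 unnamed. Macrophage-like cluster 9 has macrophage markers when set against cells of other classes, but 0 among the 10 genes that lead it against all other cells, which include 1 marker of mature dendritic cells, FSCN1.

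Levels are CPM of UMIs summed over a class in each library, given for each myeloid class with at least 50 cells in each library: macrophage-like, classical monocyte-like, nonclassical monocyte-like and cDC2-like. Sums have exact Poisson intervals, ratios exact intervals conditional on the summed UMIs and shares exact Clopper-Pearson intervals, all at 95%. With 1 library per group no test between groups can be made. Named genes are the 10 highest and 10 lowest log2 ratios of CPM + 5 in a class among genes with at least 50 CPM in either library and Poisson intervals that do not overlap, and up to 3 members of each list that are at least 2-fold apart. Genes of X inactivation, Y-linked, immunoglobulin and T cell receptor genes, genes whose presence varies between people, mitochondrial and ribosomal protein genes and genes named by a clone identifier were left out, and some genes that the rule names are not reported here. A gene with 0 UMIs in a library is given a bound at 3 UMIs.

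The 17 gene lists were fixed before the data were examined. They are lipid-associated macrophage, tissue-resident and scavenger macrophage, hypoxia and glycolysis, inflammatory cytokine and NF-kB, interferon response, MHC class II presentation, complement, extracellular matrix and protease, immune checkpoint and inhibitory receptor, monocyte and alarmin, chemokine, lysosome and phagocytosis, cholesterol efflux and sterol, metallothionein and iron, dissociation stress, proliferation and nuclear-encoded oxidative phosphorylation genes. A member counts as measured at 10 CPM or more in either library. The median log2 ratio of the measured members was set against 10000 random lists of the same size drawn from 20 bins of mean expression. The interval of a list median comes from 2000 random Poisson draws of the counts. Of the lists, 8 of the 12 monocyte and alarmin genes are also markers of some class, and 3 of the 13 complement genes are macrophage markers.

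The method was tested on simulated data for the comparison of macrophage-like cells, with 33694 genes and the depth of these libraries. Of 68 genes set 1.5-fold, 68 set 2-fold and 64 set 4-fold apart, 100% had the right direction, and the intervals held the true ratio in 100%, 92.6% and 96.9%. Of 1705 genes left equal, 0.587% had intervals that did not overlap. A list of 20 genes set 2-fold higher had a median of 0.95 and one of 20 genes left equal 0.01. The simulated counts had Poisson error only, so these values do not cover variation between donors, libraries or cells.

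The other settings fixed before were minimums of 500 and 1000 UMIs, at most 10% mitochondrial UMIs, no doublet removal, Leiden resolutions 0.5 and 2, naming each cell by its marker score, clustering each library on its own, means of per-cell CPM, median-of-ratios scaling, pseudocounts of 1 and 20, no minimum and a minimum of 50 CPM, thinning each cell to 1000 UMIs, and subtraction of free RNA. The planned share of free RNA, taken from tubule and carcinoma markers, came to 133% of the UMIs of tumor macrophage-like cells and 37.7% of the juxtatumoral ones, so it was not used. Chosen after seeing the data were a fixed share of 10% in its place, removal of the expected share of doublets, cluster 5 counted as macrophage-like, cluster 8 left unnamed, barcodes kept in both libraries left out, macrophage-like clusters 4 and 6 taken alone, and each of these settings for the shares of single classes other than macrophage-like cells.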

Results

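Single-cell RNA was measured with the 10x Genomics 3′ v2 droplet assay, in which each captured transcript carries a unique molecular identifier (UMI), in myeloid cells sorted by flow cytometry from digested human kidney tissue with a renal adenocarcinoma. One group is the tumor lesion and the other is juxtatumoral tissue, kidney tissue next to a tumor, with 1 library each. The labels do not say whether both libraries come from the same donor, so the donor may differ as well as the tissue. The juxtatumoral library held 18462128 UMIs and the tumor library 60842499 UMIs. After filtering, 2179 juxtatumoral cells with a median of 6134 UMIs and 1769 genes and 11563 tumor cells with a median of 3963 UMIs and 1227 genes were kept. With 1 library per tissue no difference has a replicate check, no test was made, and all 95% intervals cover counting error only. They are exact for levels, ratios and shares and come from random Poisson draws for list medians. Levels are UMIs per 1000000 UMIs of the same cells (CPM), summed over a class of cells, and ratios are ratios of CPM.

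The first comparison asked whether the make-up of the sorted myeloid cells differed between the tissues. Monocyte-like cells, both classes together, made up more of the myeloid cells in the tumor library and macrophage-like and cDC2-like cells made up less. Classical monocytes are known to enter tissue from the blood and to give rise to macrophages, nonclassical monocytes patrol vessels, and cDC2 present antigen to T cells. Classical monocyte-like cells, raised in S100A8, S100A9, S100A12 and VCAN, were 34.8% (32.7 to 36.9) of the 2034 myeloid cells of the juxtatumoral library and 47.0% (46.1 to 48.0) of the 10345 of the tumor library. Nonclassical monocyte-like cells, raised in FCGR3A, CDKN1C and LYPD2, were 16.9% (15.3 to 18.6) and 28.4% (27.5 to 29.2). Of these, 103 juxtatumoral and 1317 tumor cells lay in cluster 1, where 6 of 10 markers of the class were raised. The genes leading cluster 1 against cells of other classes held 1 marker of its own class and 1 of another, so its name is less certain. Macrophage-like cells, raised in C1QC, APOE and TREM2, were 34.5% (32.4 to 36.6) and 22.4% (21.6 to 23.2), a difference of -12.1 percentage points. Both monocyte classes together were 51.7% (49.5 to 53.9) and 75.4% (74.5 to 76.2), a difference of 23.7 points. Cells like type 2 conventional dendritic cells (cDC2), raised in CD1C, FCER1A, CD1E and CLEC10A, were 13.4% (11.9 to 14.9) and 2.20% (1.93 to 2.51). Mast-cell-like cells numbered 9 and 5. No cluster was named cDC1-like, mature-DC-like, pDC-like, neutrophil-like or T-cell-like.

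Cells of other types passed the myeloid sort in both libraries. B-cell-like cells were 71 of the kept juxtatumoral cells, 3.26% (2.55 to 4.09), and 4 of the tumor cells. NK-cell-like cells were 6 and 43, plasma-cell-like cells 6 and 30, endothelial-like cells 6 and 7, fibroblast-like or pericyte-like cells 6 and 6, and cells like the distal nephron and collecting duct 16 and 0, where 0 allows up to 0.0319% of the tumor cells. Unnamed clusters held 1.56% (1.08 to 2.17) of the juxtatumoral and 9.76% (9.22 to 10.3) of the tumor cells, nearly all of the latter in cluster 5, with 1115 tumor cells. The genes leading it against cells of other classes include 4 macrophage markers. Only 1 of 12 macrophage markers was raised there against all other cells. Counting that cluster as macrophage-like brought the macrophage-like difference to -5.25 points, clustering each library on its own to -4.21, naming each cell by its marker score to -3.48 and a minimum of 500 UMIs to -6.39, all with the same sign. The difference of the classical monocyte-like share was 30.4 points with a minimum of 500 UMIs, 22.2 with each library clustered on its own and 8.04 with that cluster counted as macrophage-like. The nonclassical monocyte-like share was lower in the tumor library, 13.7% and 7.09%, when each library was clustered on its own, against 12.9% and 20.2% with a minimum of 500 UMIs. The cDC2-like share was 33.6% and 2.21% with a minimum of 500 UMIs and 20.1% and 5.18% with naming by marker score. Shares may also depend on the sort gate, on the minimum UMI totals of 1922 and 2007 per cell and on the deeper juxtatumoral cells. The effects of the sort gate and of depth per cell on them were not tested.

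**Figure D1:**
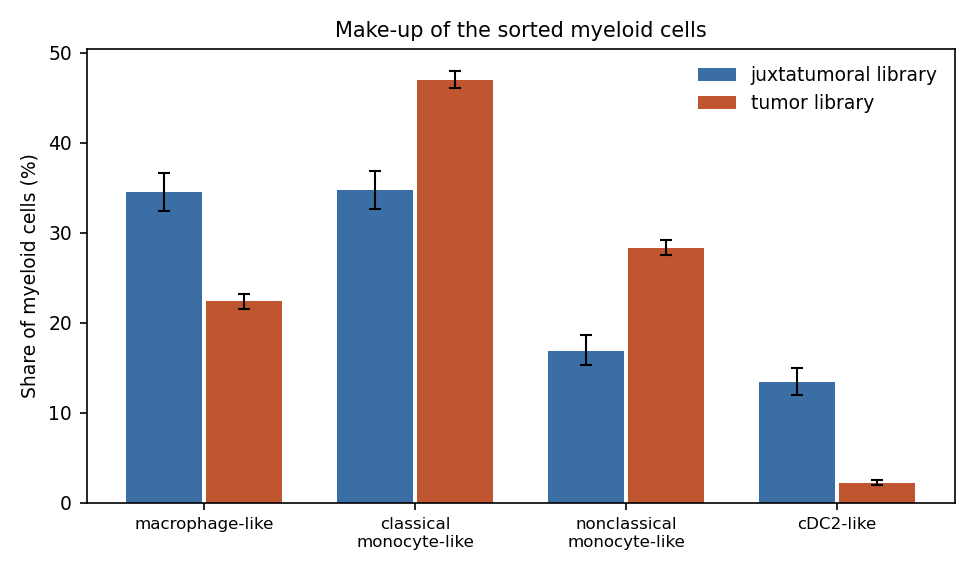
Share of each class among the myeloid cells of the juxtatumoral library (blue, 2034 cells) and the tumor library (orange, 10345 cells), in percent, with 1 library per tissue; error bars are exact 95% binomial intervals and cover counting error only. Macrophage-like cells stand at 34.5% and 22.4%, and cDC2-like cells at 13.4% and 2.20%.

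The second comparison asked which genes differed in level between macrophage-like cells of the tumor and of the juxtatumoral tissue. Juxtatumoral macrophage-like cells held far more RNA of FCGBP, SPP1, HAMP and metallothionein genes, and tumor macrophage-like cells held more RNA of PDK4, PLIN2 and of inflammatory genes led by CXCL2. The first set includes secreted and metal-binding proteins, such as osteopontin (SPP1) and the iron hormone hepcidin (HAMP). The second set includes genes of fat use and storage and of chemokines that draw neutrophils. FCGBP, which encodes a mucin-like protein that binds IgG, stood at 458 CPM (442 to 474) in the 702 juxtatumoral cells and at 0.582 CPM (0.251 to 1.15) in the 2315 tumor cells, a ratio of 786 (398 to 1823) that rests on 8 tumor UMIs. SPP1 was 15.1-fold (14.5 to 15.7) lower in the tumor library, at 226 against 3412 CPM. PDK4, a kinase that holds back the entry of pyruvate into mitochondrial oxidation, was 16.9-fold (14.1 to 20.4) higher, at 301 against 17.9 CPM. PLIN2, a coat protein of lipid droplets, was 5.14-fold (4.96 to 5.33) higher, at 2539 against 494 CPM. In GRCh38, FCGBP lies on chromosome 19 from 39863323 to 39934626 on the minus strand and SPP1 on chromosome 4 from 87975650 to 87983426 on the plus strand. PDK4 lies on chromosome 7 from 95583499 to 95596491 and PLIN2 on chromosome 9 from 19108375 to 19149290, both on the minus strand.

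The other genes with the lowest ratios were MT1E (95.2 and 2.98 CPM in the juxtatumoral and the tumor library), MT1G (28.8-fold lower), S100B (71.7 and 4.22), RGS16 (325 and 20.5), CYP27A1 (107 and 7.35), the fructose carrier SLC2A5 (71.0 and 5.82), HAMP (381 and 34.2), and SCIN (97.4 and 12.7). The other genes with the highest ratios were SDS, a serine dehydratase (5.51-fold), TNFAIP6 (5.39-fold), DNAAF1 (26.9 and 134 CPM), the neutrophil-attracting chemokine gene CXCL2 (4.25-fold), AZI2 (3.95-fold), the EGF receptor ligands EREG (3.74-fold) and AREG (3.44-fold), and CFD, the complement factor D gene (3.40-fold). Outside macrophages the juxtatumoral B-cell-like cells held 36.2 CPM of FCGBP and 222 of SPP1, and the tumor plasma-cell-like cells held 37.6 of PDK4, 288 of PLIN2 and 549 of CXCL2. The 43 tumor NK-cell-like cells held macrophage markers at 5602 CPM, against 4958 in all kept tumor cells, so they are an uncertain measure of background. They held 125 of PDK4, 1331 of PLIN2, 2028 of CXCL2 and 494 of EREG. EREG lies there above the 154 CPM of the tumor macrophage-like cells, and PDK4 above the 83.8 CPM of those in cluster 6. CXCL2 lies there near the 2097 CPM of the tumor macrophage-like cells, as do TNFAIP6 (93.4 against 95.5), AREG (1094 against 1176) and CFD (374 against 420.4).

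**Figure D2:**
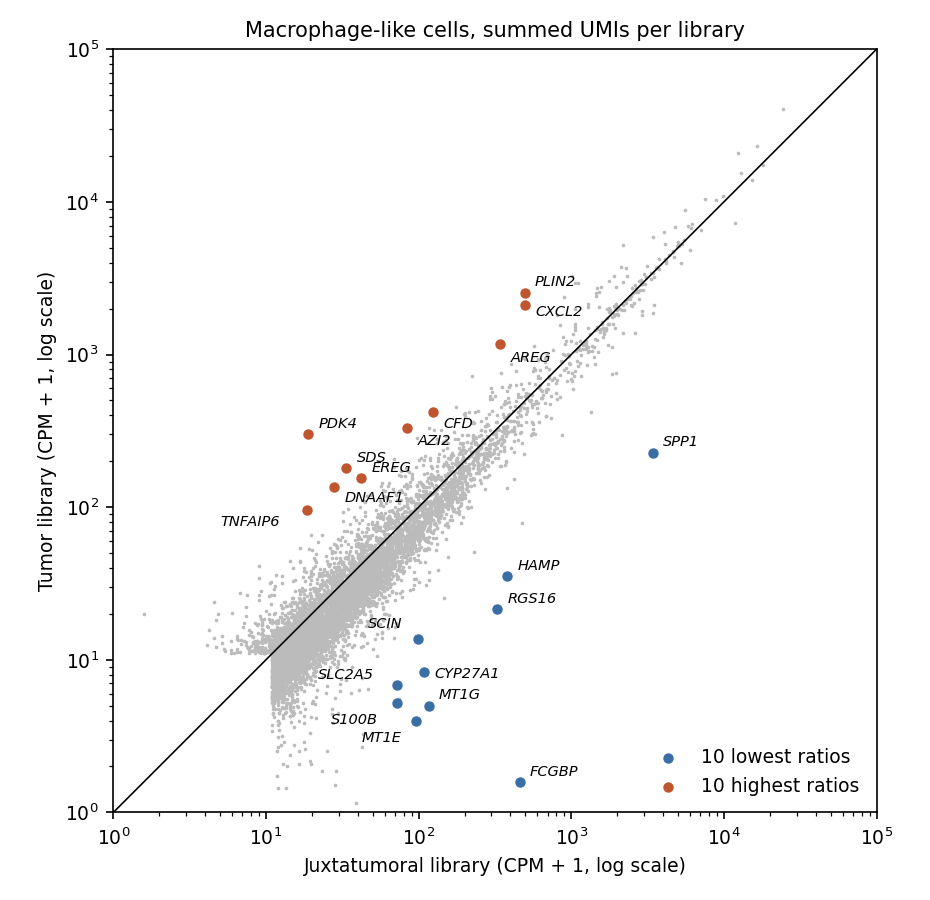
CPM of each gene in macrophage-like cells of the juxtatumoral library (horizontal axis) and of the tumor library (vertical axis), both as CPM + 1 on a log scale, for genes of at least 10 CPM in either library; the line marks equal levels, and the 10 lowest and 10 highest ratios under the naming rule are coloured. FCGBP stands at 458 and 0.582 CPM, PDK4 at 17.9 and 301 CPM; the counting intervals of both genes do not overlap.

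The class was held by different clusters in the 2 libraries. Cluster 9 held 602 of the juxtatumoral and 3 of the tumor macrophage-like cells and was set apart from other cells by FCGBP, SPP1, RGS16, MT1G, SLC2A5, SCIN and HAMP, so these genes define it. A cluster held by 1 library can be that library rather than a cell type. Clusters 4 and 6 held 58 and 42 juxtatumoral and 1068 and 1244 tumor cells. PDK4 and SEPP1 are among the genes that set cluster 4 apart, and SDS, MMP9 and TNF among those of cluster 6. Within them SPP1 was still lower in the tumor library, at 146 against 566 CPM in cluster 4 and 302 against 1983 in cluster 6, and so was FCGBP, at 0.283 against 56.9 and 0.905 against 50.2, though these juxtatumoral FCGBP levels lie near those of the B-cell-like cells. Free RNA held 3203 CPM of SPP1 in the juxtatumoral and 122 in the tumor library, and S100A8 allows it up to 34.4% of the UMIs of juxtatumoral macrophage-like cells. At that share free RNA alone would reach the SPP1 level of juxtatumoral cells in cluster 4, but not in cluster 6. PDK4 was higher in the tumor library in both, at 507 against 117 and 83.8 against 14.8 CPM, as was PLIN2, at 1939 against 443 and 3179 against 703. These 4 ratios were smaller within the clusters than in the whole class, that of PLIN2 least so. Those of EREG, SDS and HAMP were smaller too: EREG stood at 91.2 against 74.8 and 221 against 163 CPM, SDS at 127 against 41.9 and 237 against 165 and HAMP at 21.1 against 35.9 and 47.0 against 62.0.

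**Figure D3:**
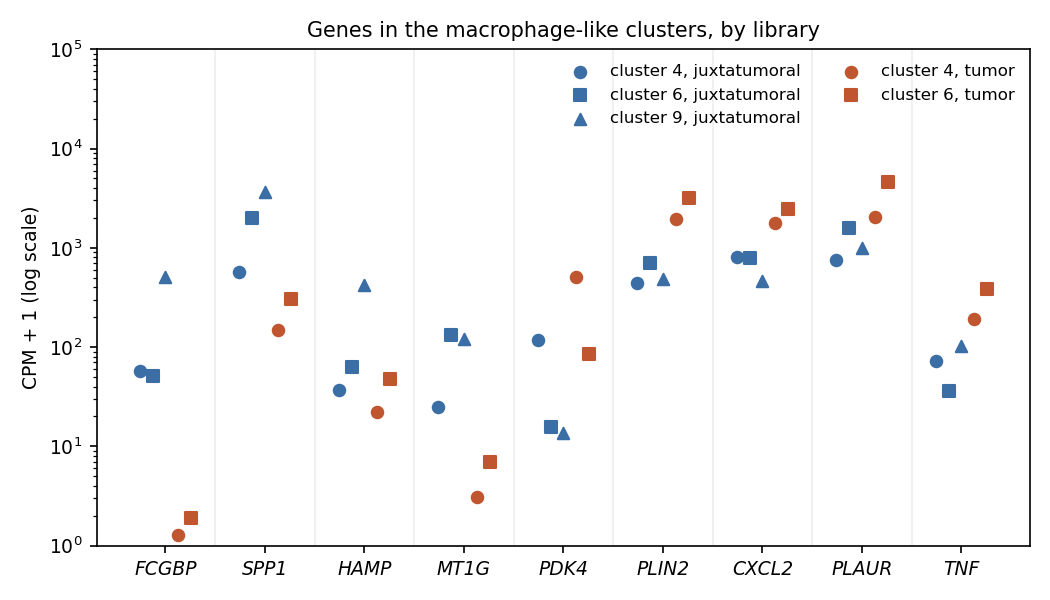
CPM + 1 on a log scale of 9 genes in the macrophage-like clusters 4, 6 and 9, each point being the summed UMIs of 1 cluster in 1 library (juxtatumoral blue, tumor orange). PLIN2 and PLAUR are higher in the tumor library in clusters 4 and 6, while HAMP stands at 418 CPM in cluster 9 and at 35.9 and 62.0 CPM in the juxtatumoral cells of clusters 4 and 6.

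Scaled to total UMIs, the median log2 ratio over 6625 measured genes was -0.32 in macrophage-like cells, and median-of-ratios scaling shifted the ratios by 0.36, so each list median of this class is also given relative to that of all genes. The inflammatory cytokine and NF-kB genes had a median log2 ratio of 0.79 (0.76 to 0.80), 1.11 above all genes and above all 10000 random lists of matched expression. Of 19 measured members 8 were at least 2-fold higher in the tumor library and 0 lower, with CXCL2 at 2097 against 493 CPM, CXCL3 at 719 against 223, TNF at 284 against 95.9 and CXCL8 at 5197 against 2188. The tumor NK-cell-like cells held CXCL2 at 2028 CPM, CXCL3 at 755, TNF at 136 and CXCL8 at 3021. The dissociation stress genes, heat shock and immediate early genes that tissue digestion is known to induce, had a median of 0.32 (0.26 to 0.38), 0.64 above all genes and at percentile 98.97. Of their 21 members 15 were positive, 6 negative and 0 at least 2-fold apart. Their UMIs were 5.18% of the juxtatumoral and 6.21% of the tumor total. Within cluster 4 alone the inflammatory median was 0.69, within cluster 6 alone 1.04 and under median-of-ratios scaling 1.22.

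Extracellular matrix and protease genes had a median of 0.21, 0.53 above all genes and at percentile 99.8, with PLAUR, the urokinase receptor gene, at 3285 against 1011 CPM and MMP19 and MMP9 2.94-fold and 2.12-fold higher, although within cluster 6 alone MMP19 and MMP9 were lower in the tumor library, with 7 of 15 members of the list at least 2-fold lower and a median of -0.90 (0.20 within cluster 4 alone). The tumor NK-cell-like cells held PLAUR at 2616 CPM. Interferon response genes had a median of 0.09, 0.41 above all genes and at percentile 99.8, but -0.16 within cluster 4 alone and -0.54 within cluster 6 alone. IFI44L was 2.15-fold higher and CXCL9 2.75-fold lower, the latter at 2.55 against 0 CPM within cluster 4 alone and 6.18 against 109 within cluster 6 alone. The metallothionein and iron genes had a median of -1.51, -1.19 relative to all genes and below all 10000 random lists, and -0.65 and -1.10 within clusters 4 and 6 alone. Of their 12 measured members 7 were at least 2-fold lower in the tumor library, among them MT1G, MT1E, HAMP and MT1H, the last at 29.8 CPM against 0 UMIs and so at least 136-fold lower. Juxtatumoral free RNA held 342, 42.2, 106 and 114 CPM of these genes. At the highest free share that S100A8 allows, 34.4%, it alone would reach the juxtatumoral levels of MT1G and MT1H in the class, but not those of MT1E and HAMP. The ferritin genes FTH1 and FTL stood at 21000.3 against 12308 and 23353 against 16464 CPM. Proliferation genes had a median of -1.46, -1.14 relative to all genes, with 9 of 13 members at least 2-fold lower, but -0.072 within cluster 4 alone and 0.34 within cluster 6 alone, where 6 members were measured. TYMS, UBE2C and ZWINT were 53.9-fold (25.6 to 136), 15.7-fold (9.96 to 26.1) and 15.8-fold (9.38 to 28.6) lower. Their levels were 30.1, 26.5 and 20.3 CPM in cluster 9. UBE2C and ZWINT within cluster 4 alone and TYMS within cluster 6 alone stood at 0 in the juxtatumoral cells, so a lower tumor level could not be seen there.

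Lipid-associated macrophage genes, 3 of whose 14 members are also macrophage markers, went both ways. SPP1 and LPL were lower and PLIN2 higher in the tumor library, and TREM2 stood at 299 against 575 CPM and APOE at 5269 against 5351. Within clusters 4 and 6 TREM2 stood at 348 against 341 and 248 against 295, and APOE at 6569 against 3527 and 3874 against 5058. Their median was 0.10, 0.42 above all genes and at percentile 95.5, but -0.15 when each cell was named by its marker score, -0.07 when the unnamed cluster 5 was counted as macrophage-like and -1.08 within cluster 6 alone, with 0.021 within cluster 4 alone, 0.33 with each library clustered on its own, 0.53 under median-of-ratios scaling and 0.21 with a minimum of 50 CPM. Tissue-resident and scavenger macrophage genes, 6 of whose 14 members are also macrophage markers, had a median of -0.15, which turned to 0.26 under median-of-ratios scaling, 0.17 above all genes and at percentile 79.2. The scavenger median was -1.33 within cluster 4 alone, with 8 of 11 members at least 2-fold lower, -0.14 within cluster 6 alone, -0.33 with means of per-cell CPM and -0.40 with cells thinned to 1000 UMIs. SEPP1, which encodes a selenium carrier protein, was 2.29-fold higher in the tumor library, with a log2 ratio of only 0.07 with means of per-cell CPM, but within cluster 4, which it helps to define, it was lower at 555 against 1832 CPM. MAF was 2.10-fold and MARCO 2.13-fold lower, although MAF was not lower within cluster 6 alone and MARCO was not lower with each library clustered on its own. Hypoxia and glycolysis genes had a median of -0.33 that turned to 0.06 under median-of-ratios scaling and lay -0.01 from all genes, with VEGFA, the vascular growth factor gene, 2.52-fold higher and GAPDH at 1125 against 1854 CPM. The hypoxia median was 0.067 within cluster 4 alone, -0.57 within cluster 6 alone, with 6 of 19 members at least 2-fold lower, and -0.18 with cluster 5 counted as macrophage-like. Clear cell carcinoma markers summed to 62.8 CPM in the tumor and 35.4 in the juxtatumoral macrophage-like cells and proximal tubule markers to 125 and 227 CPM.

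Among the remaining lists, cholesterol efflux and sterol genes had a median of -0.65, -0.33 relative to all genes and at percentile 0.275, with the sterol synthesis gene SQLE 3.73-fold lower and the cholesterol exporter gene ABCA1 3.20-fold higher in the tumor library. SQLE was not lower within cluster 4 alone, and ABCA1 stood at 30.4 against 18.0 CPM in cluster 4 and 31.2 against 26.6 in cluster 6. Immune checkpoint and inhibitory receptor genes had a median of -0.45, -0.13 relative to all genes and at percentile 8.15, with CD276, LGALS9 and LILRB1 4.18-fold, 2.07-fold and 2.18-fold lower, LILRB1 not within cluster 4 alone. Chemokine genes had a median of -0.43, -0.11 relative to all genes and at percentile 12.6, but 0.54 within cluster 4 alone, with CCL2, CCL5 and CCL8 4.06-fold, 2.70-fold and 2.90-fold lower. CCL2 was higher within cluster 4 alone and CCL8 within clusters 4 and 6 alone, at 16.1 against 0 and 7.09 against 2.95 CPM. The medians of the complement genes (-0.36, -0.04 relative to all genes), MHC class II presentation genes (-0.04, 0.28), monocyte and alarmin genes (-0.01, 0.31), lysosome and phagocytosis genes (-0.29, 0.03) and nuclear-encoded oxidative phosphorylation genes (-0.28, 0.04) all turned positive under median-of-ratios scaling. Among complement genes CFD was 3.40-fold higher and CD59 2.68-fold lower. Mitochondrial genes took 1.54% of the juxtatumoral and 1.69% of the tumor UMIs of the class.

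**Figure D4:**
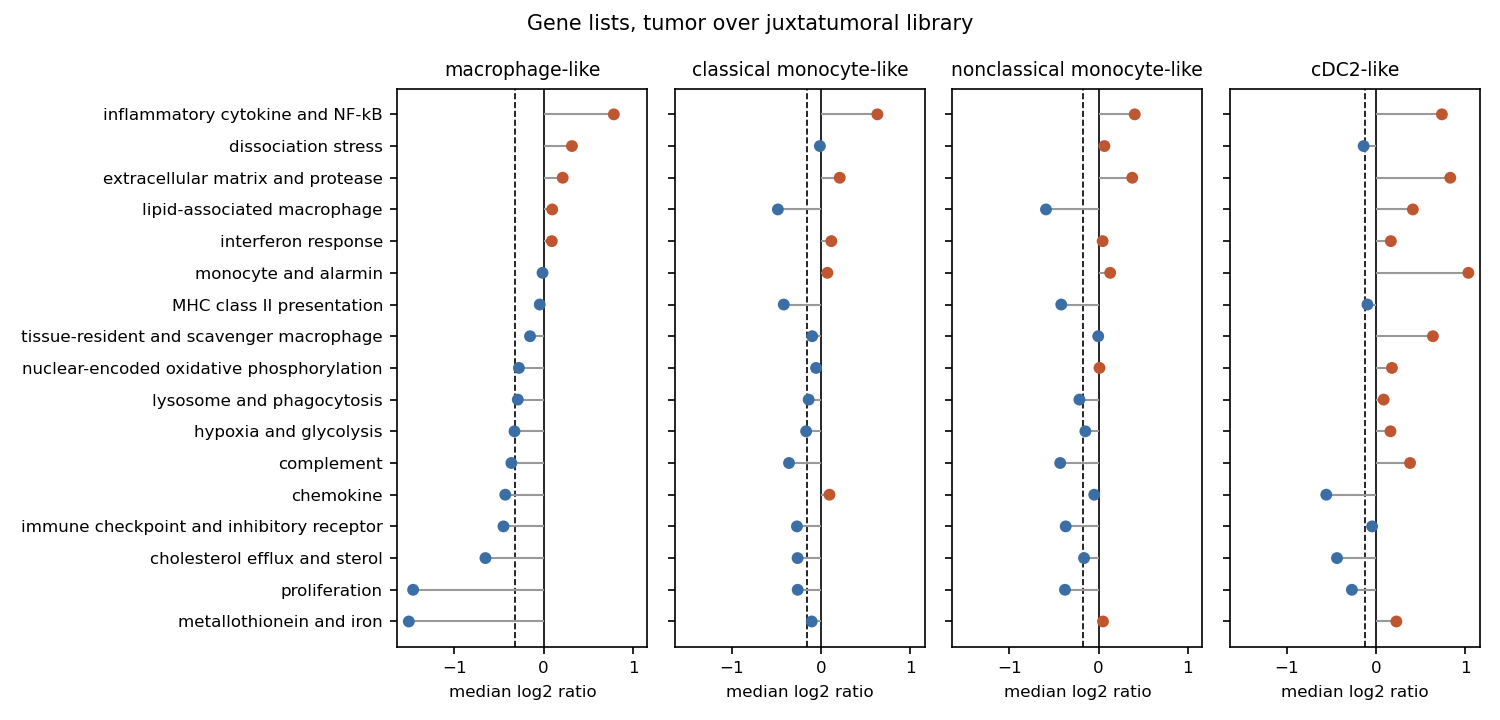
Median log2 ratio of CPM + 5, tumor over juxtatumoral library, of the measured members of each gene list in 4 classes of cells; the solid line marks 0 and the dashed line the median of all measured genes, from -0.32 in macrophage-like to -0.13 in cDC2-like cells. Inflammatory genes stand at 0.79, 0.63, 0.40 and 0.74; medians between the dashed and the solid line, and 8 of those left of the dashed line, turn positive under median-of-ratios scaling.

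The third comparison asked the same of monocyte-like and dendritic-cell-like cells. Classical monocyte-like cells, 707 juxtatumoral and 4864 tumor cells, held more RNA of CCL20, IL1A, PTGS2, LYPD3 and AREG in the tumor library. CCL20, IL1A and PTGS2 are genes that inflammation induces, and AREG encodes a growth factor for epithelium. CCL20, a chemokine gene for lymphocytes and dendritic cells, was 3.08-fold (2.98 to 3.18) higher at 3743 against 1217 CPM, and IL1A, a cytokine gene of the interleukin-1 family, was 5.33-fold (3.49 to 8.56) higher at 37.5 against 7.05. PTGS2, the inducible cyclooxygenase gene, was 2.93-fold higher and LYPD3, a cell surface protein gene, 6.73-fold. The other highest ratios were those of HAS1, a hyaluronan synthase gene (8.04-fold), NAF1 (4.90-fold), THAP2 (3.25-fold), DNAAF1 (2.89-fold), AREG (2.83-fold), TWISTNB (2.83-fold) and JMY (2.92-fold). Most juxtatumoral cells of the class lay in cluster 2, with 470 juxtatumoral and 34 tumor cells, and most tumor cells in clusters 3, 10 and 13, with 1900, 1297 and 1275 tumor and 44, 16 and 22 juxtatumoral cells. LYPD3 and MMP19 are among the genes that set cluster 10 apart, and DNAAF1, CXCL2 and IL1A among those of cluster 13.

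The median log2 ratio over 5717 genes was -0.16 in this class, and median-of-ratios scaling shifted ratios by 0.28. Inflammatory genes had a median of 0.63 (0.59 to 0.74), 0.79 above all genes and above all 10000 random lists, with 6 of 20 members at least 2-fold higher, and the dissociation stress genes had a median of -0.01, which turned to 0.31 under median-of-ratios scaling. The inflammatory median was 0.95 under that scaling. Within the stress list, of which 3 of 21 members were at least 2-fold lower, JUN, HSPA6 and HSPA1B were 2.79-fold, 2.33-fold and 2.01-fold lower in the tumor library. Among matrix genes PLAUR, MMP9 and MMP19 were 2.05-fold, 3.10-fold and 2.24-fold higher, VEGFA was 2.42-fold higher and ISG15, an interferon-induced gene, 2.04-fold. MHC class II presentation genes had a median of -0.42, at percentile 0.0600, with HLA-DPA1 at 645 against 985 CPM and CD74 at 3576 against 4839, while HLA-DOA, 3.03-fold lower, was not lower when each cell was named by its marker score. That median was -0.26 relative to all genes and -0.08 under median-of-ratios scaling. Free RNA held HLA-DPA1 at 1887 CPM in the tumor against 2790 in the juxtatumoral library and CD74 at 6061 against 9184. The proliferation genes STMN1 and TUBA1B were 3.02-fold and 2.35-fold lower.

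Several genes known from macrophages were lower in the tumor classical monocyte-like cells: SPP1 stood at 17.8 against 253 CPM, TREM2 at 6.99 against 32.7, APOC1 at 45.4 against 153, C1QC at 55.0 against 179.7, C1QB at 92.6 against 282, C3 at 14.0 against 38.8 and VSIG4 at 29.2 against 72.7. The juxtatumoral B-cell-like cells, which should lack them, held 222 CPM of SPP1, 51.7 of TREM2, 160.3 of APOC1 and 264 of C1QC. The tumor plasma-cell-like cells held 12.5, 30.1, 143 and 123 and the tumor NK-cell-like cells 50.6, 93.4, 627 and 763. The levels of TREM2, APOC1 and C1QC in the class did not exceed those of such cells of the same library. SPP1, MT1G (5.71-fold lower) and PLTP (4.31-fold lower) turned to higher in the tumor library after free RNA was subtracted at 10% of UMIs, and APOC1, C1QC and C3 did at Leiden resolution 2, where the log2 ratios of TREM2, C1QB and JUN were -0.24, -0.12 and -0.29. The turn of SPP1 was fixed by the free RNA setting. Juxtatumoral free RNA held 3203 CPM of SPP1, 10% of which exceeds the class level, and levels below 0 were set to 0. MT1E was 4.44-fold and BNIP3 2.77-fold lower. HBB, HBA2 and HBA1 (5.02-fold, 5.02-fold and 5.11-fold lower) rest on few droplets, since 1 juxtatumoral and 1 tumor droplet of cluster 8 had at least 10 hemoglobin UMIs, and HBA2 and HBA1 turned when cells were named by marker score. RGS1 was 3.63-fold lower, and ZNF90 (3.66-fold lower), MTRNR2L12 (3.48-fold lower) and NACA2 (17.4 against 66.0 CPM) are uncertain because near-identical copies of their sequences can share reads; MTRNR2L12 also leads cluster 8, with 155 juxtatumoral and 358 tumor cells.

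Nonclassical monocyte-like cells, 344 juxtatumoral and 2933 tumor cells, held more RNA of ISG15, CCL20 and of inflammatory genes as a list in the tumor library. CXCL10 and ISG15 are known targets of interferon, and OSM and CCL20 are genes of inflammatory signals. CXCL10, an interferon-induced chemokine gene, was 4.31-fold (2.94 to 6.60) higher at 53.8 against 12.5 CPM but not with a minimum of 500 UMIs per cell, and its log2 ratio was 0.0073 with a minimum of 1000 UMIs, 0.034 with the expected share of doublets removed, 0.17 with no doublets removed and 0.21 with at most 10% mitochondrial UMIs. ISG15 was 2.24-fold (2.10 to 2.38) higher at 1127 against 504, and CCL20 was 2.63-fold higher at 1805 against 686. NAF1 (5.18-fold), MCEMP1 (3.73-fold), LYPD3 (3.01-fold), the alarmin gene S100A12 (3.03-fold), DNAAF1 (2.69-fold), OSM, which encodes the cytokine oncostatin M (2.42-fold), and JMY (2.37-fold) were also higher, as were IL1A (4.14-fold), VEGFA (3.22-fold), MMP9 (3.95-fold), MMP19 (3.12-fold), ABCG1 (2.33-fold) and SEPP1 (2.03-fold). Cluster 7 held 241 juxtatumoral and 1616 tumor cells of the class and cluster 1, which ISG15 helps to set apart, 103 and 1317.

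Over 6079 genes the median log2 ratio was -0.18 in this class, with a shift of 0.25 under median-of-ratios scaling. Inflammatory genes had a median of 0.40 (0.36 to 0.50), 0.58 above all genes, and the stress genes of 0.07 (0.36 under median-of-ratios scaling), with JUN and HSPA6 2.69-fold and 2.18-fold lower in the tumor library. The inflammatory median was 1.88 with each library clustered on its own, 0.77 at Leiden resolution 2, 0.74 under median-of-ratios scaling, 0.68 with the expected share of doublets removed and 0.65 with a minimum of 1000 UMIs. Interferon response genes had a median of 0.05 at percentile 94.3, with 2 of 14 members at least 2-fold higher. Lipid-associated genes had a median of -0.59, complement genes of -0.43 and MHC class II genes of -0.42, which shrank to -0.32, -0.14 and -0.12 under median-of-ratios scaling. SPP1, APOE, APOC1, TREM2, VSIG4, C3 and PLTP were 18.0-fold, 2.83-fold, 3.21-fold, 5.03-fold, 3.18-fold, 2.99-fold and 2.21-fold lower. The juxtatumoral levels of SPP1, TREM2 and APOE, 231, 37.9 and 491 CPM, lie near or below those of the B-cell-like cells, 222, 51.7 and 636. APOE, APOC1, TREM2, VSIG4, C3 and PLTP turned to higher at Leiden resolution 2, as did ALOX5AP (3.31-fold lower) and STMN1 (2.06-fold lower). SPP1 and PLTP turned after free RNA was subtracted at 10% of UMIs, as did MT1G (4.33-fold lower) and CD59 (2.01-fold lower). For SPP1 the turn was fixed by the setting, since 10% of its 3203 CPM in juxtatumoral free RNA exceeds the class level. C1QC, at 130.3 against 352 CPM, GPR85 (3.29-fold), GSN (3.14-fold) and PFKFB4 (2.14-fold) were lower in each setting that measured them. For C1QC the juxtatumoral B-cell-like cells held 264 CPM and the tumor plasma-cell-like and NK-cell-like cells 123 and 763. Free RNA held 823 CPM of it in the juxtatumoral and 450 in the tumor library, so its levels in the class are not clear of background. NACA2, ZNF90, NBEAL1 and HNRNPA1L2 were 3.75-fold, 3.46-fold, 2.89-fold and 3.18-fold lower and are uncertain because of near-identical copies. The T and NK cell markers summed to 3.23 and 92.4 CPM in the juxtatumoral and 5.69 and 81.2 CPM in the tumor cells.

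In cDC2-like cells, 272 juxtatumoral and 228 tumor cells of cluster 0, the tumor library held less RNA of CD207 and more of alarmin and inflammatory genes. The tumor NK-cell-like cells held S100A8, CXCL2 and CCL20 at higher levels still, 3102, 2028 and 1265 CPM against 1391, 753 and 488. Those NK-cell-like cells also held macrophage markers at 5602 CPM, so they are an uncertain measure of background. CCL19, CCL17 and CCL22 encode chemokines for T cells, and S100A8, S100A9 and S100A12 encode the alarmins of monocytes. CD207, the langerin gene, was 12.1-fold (7.92 to 19.3) lower at 14.0 against 169 CPM. CD207, CCL22 and S100B are among the genes that set this cluster apart from other cells. CCL19, CCL17, CCL22 and FSCN1 are 4 of the 10 mature dendritic cell markers. CCL19 was at 55.1 CPM against 0 UMIs, hence at least 30.2-fold lower, but its log2 ratio was -0.39 at Leiden resolution 2, -0.27 with each library clustered on its own and -0.10 with naming by marker score. CCL17, CCL22 and FSCN1 were 11.1-fold (5.88 to 23.6), 3.39-fold (2.54 to 4.59) and 4.29-fold (3.03 to 6.21) lower, although CCL17 turned at Leiden resolution 2 and CCL17 and CCL22 turned with each library clustered on its own. Of the other mature dendritic cell markers LAMP3 stood at 12.8 against 51.7 CPM, EBI3 at 29.8 against 64.5, MARCKSL1 at 236 against 270.3, CCR7 higher in the tumor library at 370.2 against 178, and CD80 and IDO2 below 10 CPM in both libraries. KLRB1, IL7R and LTB, genes of T and other lymphoid cells, were 17.7-fold, 4.81-fold and 4.27-fold lower, beside T cell markers at 96.1 CPM in the juxtatumoral and 35.3 CPM in the tumor cells. The log2 ratio of KLRB1 was only -0.075 with a minimum of 1000 UMIs, -0.074 with no doublets removed and -0.12 with each library clustered on its own. S100B was 5.52-fold and the tryptophan enzyme gene IDO1 3.29-fold lower. The sterol synthesis genes MSMO1 and SQLE were 7.73-fold and 2.74-fold lower, while ABCA1 was 4.86-fold higher.

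The genes with the highest ratios in cDC2-like cells were SEPP1 (8.34-fold, 5.22 to 14.0, but a log2 ratio of 0.23 with a minimum of 500 UMIs), APOBEC3A (5.09-fold), EREG (4.51-fold), LYPD3 (4.39-fold), CCL20 (4.27-fold), ACOT7 (3.81-fold), CXCL2 (3.77-fold), S100A12 (3.61-fold), THBD (3.28-fold) and PLIN2 (3.06-fold). Over both libraries cluster 0 held 126 CPM of EREG, 82.5 of S100A12, 77.0 of THBD and 607 of PLIN2. The tumor NK-cell-like cells held 494, 393, 206 and 1331 CPM of these genes, and tumor free RNA 684, 401, 203 and 1822. LYPD3, ACOT7 and SEPP1 stood higher in cluster 0, at 61.4, 31.3 and 36.1 CPM, than in the NK-cell-like cells, at 38.9, 23.4 and 23.4. The median log2 ratio over 6518 genes was -0.13, with a shift of 0.16 under median-of-ratios scaling. Monocyte and alarmin genes had a median of 1.03, above all 10000 random lists, with 6 of 11 members at least 2-fold higher, among them S100A8 at 1391 against 584 CPM and S100A9 at 1394 against 575, in libraries whose free RNA held 3682 and 1866 CPM of S100A8. Inflammatory genes had a median of 0.74 (0.64 to 0.83), but 0.34 with a minimum of 500 UMIs and 0.42 with cells thinned to 1000 UMIs. Matrix and protease genes had a median of 0.83, with MMP9, MMP19 and THBS1 3.35-fold, 3.11-fold and 2.68-fold higher, and scavenger genes of 0.64. SOD2, CD36, VEGFA, ISG15, CFD, C5AR1 and LILRB2 were 2.48-fold, 2.69-fold, 2.45-fold, 2.29-fold, 2.82-fold, 2.47-fold and 2.36-fold higher. Over both libraries cluster 0 held SOD2, CFD, C5AR1 and LILRB2 at 761, 88.3, 113 and 44.6 CPM. The tumor NK-cell-like cells held these genes at 2009, 374, 475 and 81.7 CPM. Stress genes had a median of -0.14, at percentile 2.385, which turned to 0.05 under median-of-ratios scaling, with JUN, HSPA6 and HSPA1B 2.62-fold, 2.24-fold and 2.09-fold lower. SPP1 (7.16-fold lower) and MT1G (20.4-fold lower, 3.38 to 832, 1 tumor UMI) turned after free RNA was subtracted at 10% of UMIs, and HAMP (2.36-fold higher) turned when cells were named by marker score. The turns under subtraction can follow from the setting, since subtracted levels below 0 were set to 0.

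Over all myeloid cells together, where class shares enter the levels, the lowest ratios were again those of FCGBP (237 and 0.246 CPM), SPP1 (1729 and 81.2), S100B (106 and 5.21), RGS16 (165 and 8.95) and MT1G (64.1 and 4.10), with the cDC2 markers CD1E (103 and 8.10) and FCER1A (164 and 25.3), the mast cell tryptase genes TPSB2 (171 and 16.4) and TPSAB1 (116 and 10.8) and FSCN1 (7.21-fold lower). The highest were PDK4 (5.03-fold), LYPD3 (4.52-fold), DNAAF1 (4.50-fold), MCEMP1 (3.79-fold), EREG (3.37-fold), MMP19 (3.33-fold), CXCL2 (3.28-fold), CCL20 (3.24-fold), TNFAIP6 (3.18-fold) and THAP2 (3.17-fold). The median log2 ratio over 6445 genes was -0.26, with a shift of 0.42 under median-of-ratios scaling. Inflammatory genes had a median of 0.94, monocyte and alarmin genes of 0.67, chemokine genes of -1.10 and MHC class II genes of -0.64, in libraries of which macrophage-like and cDC2-like cells made up 34.5% and 13.4% of the juxtatumoral and 22.4% and 2.20% of the tumor myeloid cells.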

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

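The comparison of barcodes between the libraries was chosen only after the T and NK cell RNA below had been seen. The differences between classes named here were not tested.

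Lipid-associated macrophage genes stood apart between classes: their median log2 ratio, tumor over juxtatumoral, was 0.41 in cDC2-like cells, -0.48 in classical and -0.59 in nonclassical monocyte-like cells. Complement genes had medians of 0.38 in cDC2-like, -0.36 in classical and -0.43 in nonclassical monocyte-like cells. Under median-of-ratios scaling these were 0.57, -0.08 and -0.14. In the monocyte-like cells several members of both lists, such as APOC1 and C1QC, lie near the level found in cells that should lack them. Dissociation stress genes had a median of 0.32 in macrophage-like cells and of -0.14 in cDC2-like cells, the latter turning to 0.05 under median-of-ratios scaling.

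RNA of T and NK cells was plentiful where no cell was. Barcodes with 10 to 100 UMIs held T cell markers at 2593 CPM (3104 UMIs) and NK cell markers at 2382 CPM (2851 UMIs) in the juxtatumoral library, and at 1424 CPM (3057 UMIs) and 1364 CPM (2928 UMIs) in the tumor library. The kept cells held T cell markers at 23.6 and 7.87 CPM and NK cell markers at 41.4 and 62.9 CPM. Where a barcode had at least 10 UMIs in both libraries the T cell markers stood at 3194 and 3569 CPM, and where it had them in 1 library alone at 160.4 and 89.2 CPM.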

How the results depend on the processing

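No paired analysis was possible because the libraries share no donor or replicate label other than the replicate number 1 of each group. Chosen only after the data were seen were the settings with the expected share of doublets removed, cluster 5 counted as macrophage-like, cluster 8 left unnamed, shared barcodes left out, only cluster 4 or 6, all settings for the shares of single classes other than macrophage-like cells, and free RNA subtracted at 10% of UMIs. The planned subtraction with a share from tubule and carcinoma markers gave no value, since that share came to 133% of the UMIs of tumor macrophage-like cells. Values are percentage points for the macrophage-like share (-12.1 in the analysis reported) and the share of both monocyte classes (23.7), with 12.3 for classical monocyte-like, 11.4 for nonclassical monocyte-like and -11.2 for cDC2-like cells, and median log2 ratios for lists. In macrophage-like cells these were 0.10 for lipid-associated, -0.15 for scavenger, -0.33 for hypoxia and 0.79 for inflammatory genes, and for inflammatory genes 0.63 in classical monocyte-like, 0.40 in nonclassical monocyte-like and 0.74 in cDC2-like cells. The cause of the differences between settings was not tested.

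A minimum of 500 UMIs gave a macrophage-like difference of -6.39 and a monocyte-like difference of 37.8, differences of 30.4 for classical monocyte-like, 7.38 for nonclassical monocyte-like and -31.4 for cDC2-like cells, inflammatory medians of 0.74 in macrophage-like, 0.58 in nonclassical monocyte-like and 0.34 in cDC2-like cells, and a log2 ratio of -0.037 for CXCL10 in nonclassical monocyte-like cells. A minimum of 1000 UMIs gave differences of 15.4 for classical and 9.27 for nonclassical monocyte-like cells, and inflammatory medians of 0.76 in macrophage-like, 0.50 in classical monocyte-like, 0.65 in nonclassical monocyte-like and 0.84 in cDC2-like cells. At most 10% mitochondrial UMIs gave 0.76 in macrophage-like and 0.84 in cDC2-like cells. No doublet removal gave 0.81 in macrophage-like cells, and removal of the expected share 0.76 there and 0.68 in nonclassical monocyte-like cells.

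Leiden resolution 2 gave differences of 15.5 for classical monocyte-like, 7.41 for nonclassical monocyte-like and -8.996 for cDC2-like cells, a hypoxia median of -0.25 and inflammatory medians of 0.74 in macrophage-like, 0.54 in classical monocyte-like, 0.77 in nonclassical monocyte-like and 0.86 in cDC2-like cells. It reversed APOC1 (0.47), C1QC (0.12) and C3 (0.22) in classical monocyte-like cells and CCL17 (0.30) in cDC2-like cells. In nonclassical monocyte-like cells it reversed ALOX5AP (0.37), APOC1 (0.82), APOE (0.61), TREM2 (0.20), VSIG4 (0.079), C3 (0.32), PLTP (0.046) and STMN1 (0.016).

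Naming each cell by its marker score gave a macrophage-like difference of -3.48, differences of 15.7 for classical monocyte-like, 6.60 for nonclassical monocyte-like and -14.9 for cDC2-like cells, a lipid-associated median of -0.15 and inflammatory medians of 1.02 in macrophage-like, 0.58 in nonclassical monocyte-like and 0.99 in cDC2-like cells. It reversed HBA2 (0.14), HBA1 (0.021) and HLA-DOA (0.14) in classical monocyte-like cells and HAMP (-0.58) in cDC2-like cells. Each library clustered on its own gave differences of -4.21 and 15.6, with 22.2 for classical monocyte-like, -6.58 (reversed) for nonclassical monocyte-like and -8.74 for cDC2-like cells, a lipid-associated median of 0.33, a hypoxia median of -0.22 and inflammatory medians of 0.68 in macrophage-like, 0.76 in classical monocyte-like, 1.88 in nonclassical monocyte-like and 1.04 in cDC2-like cells. It reversed MARCO (0.24) in macrophage-like cells and CCL17 (0.084) and CCL22 (0.20) in cDC2-like cells.

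With cluster 5 counted as macrophage-like the differences were -5.25 and 16.9, with 8.04 for classical and 8.85 for nonclassical monocyte-like cells, the lipid-associated median was -0.066, the hypoxia median -0.18 and the inflammatory median 0.76. With cluster 8 left unnamed the monocyte-like difference was 26.8, with 15.7 for classical monocyte-like cells, the inflammatory median of classical monocyte-like cells was 0.51 and HBA1 stood at 0.055. Only cluster 4 gave a lipid-associated median of 0.021, a scavenger median of -1.33, a hypoxia median of 0.067 and an inflammatory median of 0.69. It reversed SEPP1 (-1.71), CXCL9 (0.59), LILRB1 (0.071), CCL2 (0.54), CCL8 (2.08), SQLE (0.37), UBE2C (0.079) and ZWINT (0.36). CXCL9, CCL8, UBE2C and ZWINT stood at 0 in the juxtatumoral cells of cluster 4, so a lower tumor level could not be seen. Only cluster 6 gave a lipid-associated median of -1.08, a hypoxia median of -0.57 and an inflammatory median of 1.04, and reversed MAF (0.10), MMP19 (-0.41), MMP9 (-0.77), CCL8 (0.60) and TYMS (0.12). The juxtatumoral cells of cluster 6 held CCL8 at 2.95 CPM and TYMS at 0.

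With free RNA subtracted at 10% of UMIs the hypoxia median was -0.39 and the inflammatory median 0.81 in macrophage-like cells. It reversed SPP1 (1.18), PLTP (0.25) and MT1G (0.87) in classical monocyte-like cells, SPP1 (0.19), CD59 (0.21), PLTP (0.98) and MT1G (1.06) in nonclassical monocyte-like cells, and SPP1 (2.52) and MT1G (0.14) in cDC2-like cells. Subtracted levels below 0 were set to 0, so a turn of a gene with much free RNA can follow from the setting. Means of per-cell CPM gave a scavenger median of -0.33 and inflammatory medians of 0.72 in macrophage-like and 0.60 in cDC2-like cells. Median-of-ratios scaling gave medians of 0.53 for lipid-associated, 0.26 for scavenger and 0.060 for hypoxia genes, and inflammatory medians of 1.22 in macrophage-like, 0.95 in classical monocyte-like, 0.74 in nonclassical monocyte-like and 0.92 in cDC2-like cells. A pseudocount of 20 gave an inflammatory median of 0.53 in classical monocyte-like cells, and a minimum of 50 CPM a lipid-associated median of 0.21 and a hypoxia median of -0.41. Cells thinned to 1000 UMIs gave a scavenger median of -0.40 and inflammatory medians of 0.75 in macrophage-like and 0.42 in cDC2-like cells.

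The inflammatory median was positive in each setting run for each of the 4 classes. Over the named genes of the 5 comparisons, 4273 values in 22 settings were set against those reported: 3061 lay within the counting interval, 1169 moved beyond it with the same sign and 43 reversed, for 39 of 212 pairs of a gene and a comparison, 118 different genes being named. A setting run and not named above for one of these shares or list medians left it within its counting interval. The other 13 lists were run only within clusters 4 and 6 and under median-of-ratios scaling. Within cluster 6 alone the medians of matrix (-0.90), interferon (-0.54), MHC class II (0.21), complement (0.12) and proliferation genes (0.34) had the other sign in macrophage-like cells, and within cluster 4 alone those of interferon (-0.16) and chemokine genes (0.54). In all myeloid cells together 0 reversed, 603 stayed and 323 moved.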

Other observations

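All tests below were chosen only after the result they bear on had been seen, except the gene content test at shared barcodes, whose outcome was written down before it was run.

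PLIN2, PDK4 and ABCA1, which were picked here by eye, code for a coat of lipid droplets, a kinase that favours the burning of fat over glucose and an exporter of cholesterol. PLIN2 stood at 1939 and 3179 CPM in the tumor cells of clusters 4 and 6, against 443 and 703 in the juxtatumoral cells, and PDK4 at 507 and 83.8 against 117 and 14.8. ABCA1 stood at 30.4 and 31.2 against 18.0 and 26.6, ratios below the 3.20-fold of the whole class. These tumor levels of ABCA1 lie below the 35.0 CPM of the tumor NK-cell-like cells and the 61.2 CPM of tumor free RNA. The fixed lists do not share this direction: of lipid-associated genes 1 was at least 2-fold higher and 2 lower in tumor macrophage-like cells, and of cholesterol efflux and sterol genes 1 was higher and 4 lower. No explanation was tested.

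The juxtatumoral macrophage-like cells of cluster 9 combined SPP1 (3647 CPM), FCGBP (502), HAMP (418) and RNA of cell cycle genes such as TYMS (30.1), UBE2C (26.5) and ZWINT (20.3). The levels of these cell cycle genes were 0 to 5.99 CPM in the juxtatumoral cells of clusters 4 and 6. Whether the combination belongs to a macrophage state of the juxtatumoral tissue or to that library was not tested, since each tissue has 1 library.

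Tumor-library UMIs lay at the barcodes of juxtatumoral cells. These 2112 barcodes held 115 UMIs on average in the tumor library against 4.81 elsewhere, a ratio of 24.0, which free RNA spread over droplets does not give. Their UMIs in the libraries had a correlation of r 0.962, and FCGBP and SPP1 together stood there at 0.938 times their level in the juxtatumoral macrophage-like cells (3630 and 3870 CPM). Reading of molecules of 1 library under the sample index of the other, at 1.59% of the UMIs of those cells, is a candidate explanation for these. In the other direction the signal was weaker: the juxtatumoral library held 24.3 UMIs on average at barcodes of tumor cells against 2.90 elsewhere (8.36 times), with r 0.658, an excess of 0.457%, and FCGBP and SPP1 at 1.65 times their level in tumor macrophage-like cells. All barcodes with 10 to 100 UMIs coincided between the libraries 4.21 times as often as by chance. Those with a T cell marker UMI coincided 69.4 times as often as by chance, so this RNA may come from another library sequenced with them. That ratio was not computed for NK cell markers, and no biological explanation was tested.

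Cluster 5, with 1115 tumor cells, was led by macrophage genes such as APOC1, APOE and C1QC against cells of other classes. Only 1 of 12 macrophage markers was raised against all other cells. Its leading genes held 0 markers of another class, so a mixture with monocyte genes was not shown. Of 1820 genes 0% stood above 1.5 times their highest level in the macrophage-like and monocyte-like clusters, against 0.0581% to 4.45% for those clusters themselves. Droplets with a macrophage and a monocyte would give a low share, but so would single cells between them. Its median of 7239 UMIs was 1.39 times the highest of theirs and lay below the sum of the macrophage-like and classical monocyte-like medians, 8296. In the tumor library this RNA content is above that predicted for single cells between monocyte and macrophage. The 21 juxtatumoral cells of the cluster, however, had a median of 7181 UMIs, below the 9197 of juxtatumoral macrophage-like cells. Most of those were the 602 cells of cluster 9, with a median of 9667 UMIs, a cluster nearly absent from the tumor library. The juxtatumoral cells of clusters 4 and 6 had medians of 5513 and 6886 UMIs, below that of cluster 5. Droplets with a macrophage and a monocyte are a candidate source, since the doublet caller removed 0.00865% of the tumor cells. The cluster holds 9.64% of the tumor cells, though, and the expected 9.25% covers doublets of every kind. Neither source was settled. A separate cell type with much RNA and no gene of its own was not tested.

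Inflammatory genes had positive medians in 4 classes, and 3 technical explanations were examined. Free RNA of the tumor library, rich in CXCL8 (6825 CPM) and CXCL2 (4089 CPM), leaves a median of 0.81 in macrophage-like cells when 10% of UMIs are subtracted, and S100A8 caps the free share of tumor macrophage-like cells at 14.0%. Harsher digestion of the tumor is a candidate explanation in macrophage-like cells, where stress genes, which it would raise, had a median of 0.32. Within clusters 4 and 6 alone 15 and 13 members of the stress list were positive and 6 and 8 negative. JUN, at 3664 against 4497 and 394 against 1031 CPM, and HSPA6, at 2669 against 3844 and 883 against 1460, were lower in both clusters. In cDC2-like cells it cannot be told apart from other explanations. The stress median of -0.14 lay at percentile 2.385 of random lists of matched expression. It lay near the median of all genes (-0.13), though, and turned to 0.05 under median-of-ratios scaling, with 9 positive and 12 negative members. The stress medians of classical and nonclassical monocyte-like cells, -0.01 and 0.07 or 0.31 and 0.36 under that scaling, leave digestion open there. A difference between the libraries other than the tissue cannot be told apart from the tissue with 1 library each, and a difference between the tissues also remains open and untested.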
